A study of Homo sapiens with 4 samples.

How the data were processed

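Total RNA of INA6 cells had been labelled with Cy3 and hybridised to 4 one-colour Agilent arrays, 1 per condition (pH 7.4 or pH 6.8, without or with valproate), per the labels. Samples were grouped by the pH and the treatment that the labels give. The valproate dose is 100 µg/mL per the labels' treatment protocol, the sample descriptions and the design text, while the source name field of the labels writes mg/mL; the value in µg/mL is used here. The array files were annotated on hg19 (GRCh37), per the file headers, and the table of genes used for names is of GRCh38.p14, so no coordinates are printed.

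The deposited scanner files hold spot intensity values made by the authors with Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes. The processed signal in them is an intensity that the software had background-subtracted and detrended within each array and that was not normalized between arrays, per the file headers. The median signal and the local background signal are uncorrected brightness values, per the file headers, and the other columns used are flags of 0 or 1 (well above background, saturated, outlier), per the file headers. The deposited series table holds log2 values of the authors; set against the scanner values of the same arrays, 99.1 to 99.2% of 34118 probes lay within 0.01 of a constant offset, so its scale and its centring on each array's 75th percentile were settled from the data. Its column medians were -3.76, -3.52, -3.32 and -3.61 in the order pH 7.4 without and with valproate, pH 6.8 without and with valproate, and it holds signals, not ratios, so that no direction stayed open.

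Spots flagged as outliers and control spots were left out and spots of one probe averaged, which left 34118 probes after 9 with every spot flagged on an array were dropped. The values used are log2 of the processed signal minus each array's 75th percentile over probes (626.6, 605.1, 588.3 and 603.9 in the same order). Array accessions were matched, without versions, to the RefSeq gene table, which gave 25416 probes 1 gene symbol and left 8702 without one. These made 19480 genes with a symbol and 8291 features without. A gene's value is that of its brightest probe over the 4 arrays; among 2911 genes with 2 probes well above background, the 2 brightest probes correlated across genes at 0.79, 0.67, 0.74 and 0.78 in the 4 pairwise comparisons. A gene counts as well above background where that probe is, except that any of a gene's probes counts in the choice of genes named by a bound, in medians with dim signals raised, in counts of genes by the arrays they were seen on and in tests on chosen genes (histone deacetylase inhibition, other cells), which gives 15606 genes on all 4 arrays. By the first rule 15586 genes were so on all 4 arrays, 17234 on at least 2 and 18952 on at least 1.

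The pairwise comparisons use genes well above background on at least 1 of the 2 arrays and count differences of at least 2-fold, without a test, since there is 1 array per group. A gene not well above background on 1 of the 2 arrays has only a bound, computed from the bright array's value against the higher of the dim array's lowest signal well above background and the dim gene's own signal. The averaged differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on pH and valproate, two-sided, with Benjamini-Hochberg adjustment, on genes well above background on at least 2 arrays. In data simulated for the acid difference over 17234 genes with noise like that between spots, 100% of genes changed by 2-fold and 100% of those changed by 4-fold were recovered with 11 false calls; with noise as large as the measured interaction, 0% of either were recovered. The interaction and the correlations use genes well above background on all 4 arrays.

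Before the data were examined, 32 gene lists were fixed, each described by the median of its members well above background on at least 1 array and by the percentile of that median among 10000 random lists of the same size matched on mean signal in 10 bins. The lists were cholesterol synthesis and uptake, fatty acid synthesis, amino acid stress (ATF4), endoplasmic reticulum chaperones, heat shock proteins, glycolysis, hypoxia-inducible factor targets, acid sensors, proton, lactate and bicarbonate transport, lysosome and autophagy, FOXO targets, histone deacetylases and Sp factors, death receptors, the BCL2 family, p53 targets, mitosis, DNA replication (E2F), ribosome biogenesis (MYC), replication-independent histones, metallothioneins, neuronal REST targets, IL6-STAT3, NF-kB, interferon-stimulated genes, NRF2, plasma cell identity, myeloma bone disease factors, and markers of T and NK, myeloid, B, stromal and erythroid cells. Of 655 entries in them 12 had no probe here. The step was tested on the acid differences without valproate, shuffled over 18952 genes. There 10 of 10 lists moved by 1 log2 unit lay outside the central 95% of random lists, and 4 of 100 unmoved lists did. Shuffling removes the co-regulation of list members, so the 4 of 100 gives no rate of false findings for the real lists. Beside the medians, a second median was computed with dim signals raised to each array's lowest signal well above background, which was decided after the data were seen.

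The genes named in the text follow a rule fixed before the data were examined, with exceptions said where they stand. The rule takes the 12 highest and 12 lowest genes by the smaller of the differences in both pairs for acid and for valproate, the 3 highest and 3 lowest genes and bounds of each pairwise comparison, the 6 highest and 6 lowest by interaction, up to 4 members of each list with the largest averaged difference, and TNFRSF10A, TNFRSF10B, TRPV1, HDAC1, SP1, the acid sensors and the histone deacetylases. Genes without a symbol, or with a bare LOC or XLOC identifier, are not named and stand in no order of highest or lowest, although the counts include them. Not every gene that the rule takes is printed.

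The alternatives were quantile normalization, the deposited series table, the mean of a gene's probes, other filters on background, fold thresholds of 1.5 and 4, adjusted p of 0.1 and 0.2, limma without the trend and random lists not matched on signal. Normexp on the mean spot signal was planned, but the files have no such column, so it was run on the median signal with an offset of 50. On the array at pH 7.4 with valproate its first fit gave a background mean of -399, since the lowest signal minus local background was -12866, so flagged backgrounds (201, 69, 46 and 417 spots in the order above) were replaced by the array's median background, which gave -10.2. That change was made after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.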

Results

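Gene expression was measured in INA6 cells, a human multiple myeloma line (a cancer of antibody-secreting plasma cells) whose growth depends on interleukin-6. The cells had been cultured for 12 hours at pH 7.4 or at pH 6.8, without valproate or with 100 µg/mL of it. Valproate is an anticonvulsant that inhibits histone deacetylases. Each of the 4 conditions was hybridised to 1 one-colour array, and all 4 arrays lay on 1 slide. The number of arrays limits the precision. With 1 array per group no difference below has a replicate check, and nothing in the labels says whether the 4 RNA samples came from separate cultures, so any p-value would measure only the spread between these arrays. Probes well above background made up 58.3% of all probes at pH 7.4 without valproate, 62.4% at pH 7.4 with valproate, 64.3% at pH 6.8 without valproate and 59.9% at pH 6.8 with valproate. No spot was saturated. Probes printed 10 times on each array had a median standard deviation between spots of 0.0586 to 0.0639 on the log2 scale, which covers the spot-to-spot error within an array and nothing else. All differences are log2 differences of normalized signal, and groups are named as the labels name them. The labels conflict on the dose, since 1 field gives it in mg/mL and the others in µg/mL.

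The first comparison, named in the title of the series, asked what acid did to otherwise untreated cells. It takes the labels as given, while an exchange of the valproate labels of the 2 arrays at pH 6.8 is left open further below. Under that exchange this comparison would be acid with valproate against neither. The arrays for acid alone would then differ at least 2-fold in 109 of 15586 genes, against 2612 as labelled. Without valproate, genes of ribosome production, DNA replication, protein folding and plasma cell identity were lower at pH 6.8 than at pH 7.4. All 25 measured genes of nucleolus and ribosome biogenesis, which MYC activates, were lower, 23 of them at least 2-fold, and their median difference was -1.59. Examples were RRP9, a component of the particle that processes ribosomal RNA, at -2.22, the ribosome assembly factors NOP16 at -2.19 and MRTO4 at -2.16, and RRS1 at -1.74. All 29 measured genes of DNA replication and G1/S (E2F targets) were lower, 12 at least 2-fold, with a median of -0.93; the uracil-DNA glycosylase UNG stood at -1.97 and UHRF1, which maintains DNA methylation, at -1.60. Of the 17 heat shock proteins 13 were lower, 7 of them at least 2-fold, with a median of -0.93, among them the chaperones HSPA8 at -2.07, HSPH1 at -1.99 and DNAJA1 at -1.41.

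Of 23 genes of plasma cell identity 18 were lower at pH 6.8 without valproate, 9 at least 2-fold, with a median of -0.72. TNFRSF13B and TNFRSF17, receptors for plasma cell survival factors, stood at -1.74 and -1.69, and the transcriptional co-activator POU2AF1 at -1.37. Outside the rule for named genes, and chosen after their values were seen, IRF4, a transcription factor on which myeloma cells depend, stood at -2.28 and the plasma cell surface proteoglycan SDC1 at -2.05. MYC, chosen likewise and already counted among the ribosome biogenesis genes above, stood at -1.44. All 22 chaperones and degradation factors of the endoplasmic reticulum were lower, 3 at least 2-fold, with a median of -0.61 and HSP90B1 at -0.92. Of 23 genes of cholesterol synthesis and uptake 19 were lower with a median of -0.56. Of 24 amino acid stress genes (ATF4 targets) 17 were lower with a median of -0.48, although VLDLR stood at 2.12 and DDIT4, an inhibitor of mTORC1, at 1.20.

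Metallothioneins, which bind zinc and copper, stood highest among the groups. Of 11 measured members 10 were at least 2-fold higher at pH 6.8 without valproate, with a median of 2.80, MT1M at 4.84 and MT2A at 3.01. The sequences of these genes are so alike that a probe for 1 of them may bind others, so the members are not separate observations. Targets of FOXO factors, which PI3K-Akt signalling represses, were higher in 16 of 18 cases with a median of 0.77; TXNIP, which restrains glucose uptake, stood at 3.37, YPEL3 at 2.41 and the cyclin CCNG2 at 2.06. Hypoxia-inducible factor targets were higher in 12 of 17 cases with a median of 0.52, including the carbonic anhydrase CA9 at 2.39, NDRG1 at 1.93 and the mitophagy receptor BNIP3 at 1.37. The other 5 were lower. Among them, outside the rule for named genes and chosen after their values were seen, were PDK1 at -0.81, ADM at -0.72 and VEGFA at -0.47. Targets of p53 were higher in 19 of 25 cases with a median of 0.47, including the cytokine GDF15 at 2.48. Of 20 NF-kB targets 13 were higher with a median of 0.56 and TNFAIP2 at 2.57, and of 22 interferon-stimulated genes 16 were higher with a median of 0.52 and OASL at 1.96. Of 25 lysosome and autophagy genes 18 were higher with a median of 0.23 and the protease gene CTSF at 3.18. Of 15 replication-independent histone genes 8 were higher with a median of 0.17.

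Of the lists that mark other cells or tissues, the neuronal, fibroblast and erythroid lists lay outside the central 95% of random lists matched on signal, and the B cell, T and NK cell, and myeloid lists inside it. Of 18 neuronal genes repressed by REST 15 were higher at pH 6.8 without valproate, with a median of 0.86 and the synaptotagmin gene SYT11 at 3.93. Of 10 fibroblast and stromal cell markers 9 were higher with a median of 2.36, but only 4 of the 10 were well above background on all 4 arrays (THY1 at 1.15, TAGLN at 0.40, FBLN1 at 0.27, which turned its sign with quantile normalization, and COL5A1 at -0.33), and with dim signals raised to each array's lowest signal well above background the median was 0.72. B cell markers had a median of 1.02 (0.83 with dim signals raised) and T and NK cell markers a median of 0.77, with CD3D at 2.24. Myeloid markers had a median of -0.26, and 10 of 11 erythroid markers were lower with a median of -0.53. Of 15 myeloma bone disease factors 11 were higher with a median of 0.90 (0.28 with dim signals raised); TNFSF13B, a survival factor of B-lineage cells, stood at 3.05 and the protease gene MMP9 at 2.05.

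Among single genes with a symbol that were well above background on both arrays, PGF, a growth factor of the VEGF family, stood at 5.42, the leukocyte surface antigen CD52 at 5.18 and COXFA4L3 at 5.04. The lowest were the mitochondrial phospholipase gene PLD6 at -4.00, FAM3A at -3.87 and the monocarboxylate transporter gene SLC5A12 at -3.69. Another 3 genes were not well above background at pH 7.4 and so have only a bound, with DACT3, an antagonist of Wnt signalling, at least 60.1-fold higher, GOLGA6L6 at least 47.9-fold higher and the aldo-keto reductase AKR1C3 at least 35.8-fold higher. In the other direction the kinase gene CAMK2A was lower by at least 3.33 log2 units, EDN3 at least 7.15-fold lower and PCDHB16 at least 6.94-fold lower. Of the genes fixed in advance, the TRAIL receptor genes TNFRSF10A and TNFRSF10B stood at -0.90 and 0.61, the proton-sensing receptor gene GPR65 at 1.70, the ion channel gene TRPV1 at -0.57, HDAC4 at -1.18, HDAC7 at -1.08, SP1 at -0.05 and HDAC1 at -0.24, of which HDAC1 turned its sign with quantile normalization in this and the other 3 pairwise comparisons.

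Among 18194 genes well above background on at least 1 of the 2 arrays without valproate, 2561 were at least 2-fold higher at pH 6.8, 880 of them by bound only, and 1165 were at least 2-fold lower, 191 by bound only. With normexp background correction these counts were 1116 and 684. In the main counts 68.7% of these genes were higher, and 57.2% with quantile normalization. The medians of 19 of the 32 gene lists lay outside the central 95% of the medians of 10000 random lists matched on signal, 11 above and 8 below; such percentiles are a description of these arrays and not p-values. The other 13 lists, with their medians, were B cell markers and T and NK cell markers (above), myeloid markers (above), fatty acid synthesis at -0.35, glycolysis at -0.19, acid sensors at 0.04, proton, lactate and bicarbonate transport at 0.19, histone deacetylases and Sp factors at -0.05, death receptors at -0.21, the BCL2 family at 0.07, mitosis at -0.24, IL6-STAT3 targets at -0.06 and NRF2 targets at -0.14. The medians of glycolysis, acid sensors and mitosis turned their sign with quantile normalization.

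**Figure D1:**
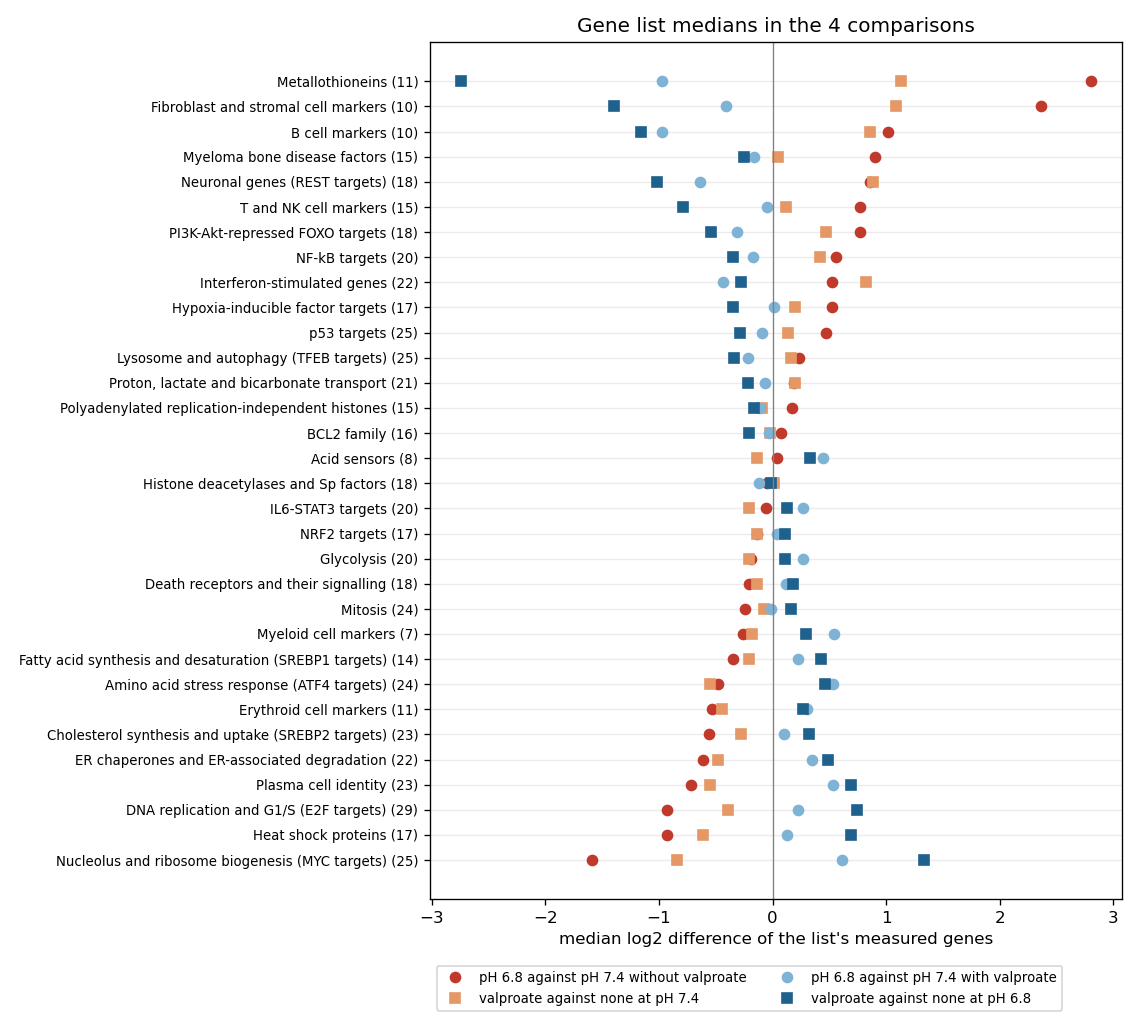
Median log2 difference of the measured genes of each of the 32 lists (number of genes in parentheses) in the 4 pairwise comparisons, each from 1 array per group; circles compare pH 6.8 with pH 7.4 and squares compare valproate with none. The ribosome biogenesis list ran from -1.59 to 1.33 and the metallothioneins from -2.74 to 2.80, with the orange and red points on 1 side and the blue points on the other.

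The same comparison was made among cells given valproate, where most of these groups stood on the other side of 0. All 25 genes of nucleolus and ribosome biogenesis were higher at pH 6.8 than at pH 7.4, 1 of them at least 2-fold, with a median of 0.61, RRP9 at 0.90 and NOP16 at 0.73. Plasma cell genes were higher in 17 of 23 cases with a median of 0.53, amino acid stress genes in 21 of 24 with a median of 0.53, and endoplasmic reticulum genes in 22 of 22 with a median of 0.35. TNFRSF13B stood at 0.62 and CCND1, the cyclin of the G1 phase, at 0.76. Metallothioneins were lower in 10 of 11 cases, 5 at least 2-fold, with a median of -0.97 and MT1M at -1.72. Neuronal genes had a median of -0.64 with SYT11 at -2.37, interferon-stimulated genes a median of -0.44, FOXO targets -0.31 with YPEL3 at -1.06, and lysosome genes -0.22 with CTSF at -1.70. B cell markers had a median of -0.97 (-0.14 with dim signals raised), fibroblast markers -0.41 (0.03 with dim signals raised), myeloid markers 0.54, erythroid markers 0.30 and T and NK cell markers -0.05.

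Among genes with a symbol and well above background on both arrays, the highest at pH 6.8 among cells with valproate were the keratin-associated KRTAP5-5 at 2.82, SLITRK6 at 2.69 and UMODL1 at 2.64, and the lowest were NGEF at -3.42, COXFA4L3 at -3.36 and the receptor phosphatase gene PTPRF at -3.33. By bound, the melanocyte antigen MLANA was at least 13-fold higher, TDRD9 at least 11-fold and EFCAB9 at least 9.97-fold, while AKR1C3 was at least 17.8-fold lower, KLK1 at least 10.4-fold and PRKAR2B by at least 3.42 log2 units. TNFRSF10A stood at 0.42, TNFRSF10B at 0.41, GPR65 at -1.11 and HDAC4 at 1.40. Among 17897 genes compared, 530 were at least 2-fold higher, 326 by bound only, and 1187 at least 2-fold lower, 401 by bound only. With normexp on the median signal, which changed several choices at once, these counts were 98 and 330, and among genes well above background on all 4 arrays 175 and 718. Of the 32 list medians, 14 lay outside the central 95% of random lists, 7 above and 7 below. Acid sensors had a median of 0.44, glycolysis genes 0.27 and replication-independent histones -0.11. The lists not yet named lay between -0.17 for NF-kB targets (-0.07 with dim signals raised) and 0.27 for IL6-STAT3 targets.

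The next comparison set valproate against none at pH 7.4. Most groups lay on the same side of 0 as in acid without valproate, and both differences use the same array at pH 7.4 without valproate. Replication-independent histones did not, with a median of -0.09 and 6 of 15 higher, against 0.17 in acid. Nor did acid sensors (-0.14, against 0.04 in acid), the BCL2 family (-0.02 against 0.07) or histone deacetylases and Sp factors (0.01 against -0.05). The medians of these exceptions at pH 7.4 lay inside the central range of random lists. All 25 genes of nucleolus and ribosome biogenesis were lower with valproate, 8 at least 2-fold, with a median of -0.84 and RRP9 at -1.35. Heat shock proteins had a median of -0.61 with HSPA8 at -1.24, plasma cell genes -0.55 with POU2AF1 at -0.82, amino acid stress genes -0.55, endoplasmic reticulum genes -0.48 with 22 of 22 lower, erythroid markers -0.45 and E2F targets -0.39 with 27 of 29 lower. Metallothioneins were higher in 10 of 11 cases, 7 at least 2-fold, with a median of 1.13 and MT1M at 2.53. Neuronal genes, which histone deacetylases help REST to silence, were higher in 14 of 18 cases with a median of 0.88 (0.63 with dim signals raised), SYT11 at 2.96 and the tubulin gene TUBB2A at 1.65. Interferon-stimulated genes had a median of 0.82 (0.69 with dim signals raised) with IFI44 at 1.55, FOXO targets 0.47, NF-kB targets 0.42 (0.27 with dim signals raised), hypoxia-inducible factor targets 0.20 and lysosome genes 0.16. Proton, lactate and bicarbonate transport had a median of 0.20, which was -0.09 with dim signals raised. Of the markers of other cells, B cell markers had a median of 0.86 (0.42 with dim signals raised), fibroblast markers 1.09 (0.15 with dim signals raised), T and NK cell markers 0.12, which turned its sign with quantile normalization, and myeloid markers -0.18.

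Among genes with a symbol and well above background on both arrays, the highest with valproate at pH 7.4 were COXFA4L3 at 3.70, PGF at 3.59 and CD52 at 3.46, and the lowest were the keratin gene KRT17 at -2.65, PLD6 at -2.48 and SLC5A12 at -2.43. AKR1C3 was at least 18.5-fold higher, KLK1 at least 15.7-fold and BSND at least 15.4-fold, and CAMK2A was at least 10.4-fold lower, EDN3 at least 7.41-fold and PCDHB16 at least 7.19-fold. TNFRSF10A stood at -0.60, TNFRSF10B at -0.10, HDAC1 at -0.06 and HDAC4 at -1.28. Among 17655 genes, 1474 were at least 2-fold higher, 507 by bound only, and 417 at least 2-fold lower, 190 by bound only, and with normexp 456 and 118. The share that was higher in the main counts was 77.9%, and 67.0% with quantile normalization. List medians lay outside the central 95% of random lists for 16 lists, 9 above and 7 below.

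At pH 6.8 the comparison of valproate with none ran the other way. All 25 genes of nucleolus and ribosome biogenesis were higher with valproate, 22 at least 2-fold, with a median of 1.33, NOP16 at 1.85 and MRTO4 at 1.78. All 29 E2F targets were higher with a median of 0.74 and UNG at 1.56. Plasma cell genes had a median of 0.69 with TNFRSF13B at 1.71 and TNFRSF17 at 1.67, heat shock proteins 0.69 with HSPA8 at 1.74, endoplasmic reticulum genes 0.49 with 22 of 22 higher, amino acid stress genes 0.46, fatty acid synthesis 0.43 with the carboxylase gene ACACA at 1.55, and cholesterol synthesis 0.32. Metallothioneins were at least 2-fold lower in 10 of 11 cases with a median of -2.74 and MT1M at -4.04. Neuronal genes had a median of -1.02 with TUBB2A at -3.53, FOXO targets -0.54 with TXNIP at -2.14, hypoxia-inducible factor targets -0.35 with NDRG1 at -1.63, NF-kB targets -0.35, lysosome genes -0.34, p53 targets -0.29 with GDF15 at -2.57, interferon-stimulated genes -0.28 and replication-independent histones -0.16. T and NK cell markers had a median of -0.79, B cell markers -1.16 (-0.80 with dim signals raised), fibroblast markers -1.40 (-0.67 with dim signals raised), myeloid markers 0.29 and erythroid markers 0.27.

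Among genes with a symbol and well above background on both arrays, the highest with valproate at pH 6.8 were FAM3A at 4.05, PLD6 at 3.84 and SLC5A12 at 3.58, and the lowest were GOLGA6L6 at -4.94, COXFA4L3 at -4.71 and PGF at -4.62. UMODL1 was at least 12.6-fold higher and MLANA at least 12.5-fold, while DACT3 was at least 57.7-fold lower, AKR1C3 at least 34.4-fold and SBK1 at least 27.0-fold. TNFRSF10A stood at 0.72, TNFRSF10B at -0.30, GPR65 at -1.52, HDAC1 at 0.19, HDAC4 at 1.30 and HDAC7 at 1.16. Among 18372 genes, 993 were at least 2-fold higher, 297 by bound only, and 2119 at least 2-fold lower, 693 by bound only, and with normexp 438 and 888. The share that was higher in the main counts was 31.9%, and 42.2% with quantile normalization. List medians lay outside the central 95% of random lists for 19 lists, 7 above and 12 below.

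Of 15586 genes, 24.2% had the same sign in both acid comparisons and 15.8% in both valproate comparisons. The genes named for both pairs are among the 12 highest and 12 lowest with a symbol by the smaller of their 2 differences. Higher at pH 6.8 both without and with valproate were FAXDC2 (1.28 and 2.16), the antisense transcript ZEB1-AS1 (1.23 and 1.14), PAPSS2, which makes the sulfate donor of sulfation reactions (1.15 and 1.13), FAM177B (1.11 and 1.06), TRIM54 (1.03 and 2.41), the imprinted gene PEG3 (1.56 and 1.01), SYCE1L (0.90 and 1.34), SOX30 (0.87 and 1.07), the chromatin remodeller gene CHD5 (1.48 and 0.86) and the early response gene EGR3 (1.44 and 0.85). Lower in both were POF1B (-0.80 and -0.90), FBXL19-AS1 (-0.70 and -1.23), the ribonuclease P subunit gene RPP30 (-0.58 and -0.59), the helicase gene EIF4A2 (-0.89 and -0.58), HIC1 (-0.96 and -0.54) and the receptor gene IL13RA1 (-0.94 and -0.52). POF1B did not keep its direction without valproate when the mean of its probes was taken. Averaged over valproate, hypoxia-inducible factor targets had a median acid difference of 0.34 with 14 of 17 higher, but that average came mostly from the pair without valproate, since with valproate their median was 0.01 and CA9, for example, stood at -0.04. Metallothioneins averaged 0.94, FOXO targets 0.22, ribosome biogenesis -0.40 and E2F targets -0.34, and each is what was left of medians of opposite sign without and with valproate.

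Higher with valproate at pH 7.4 and at pH 6.8 were the basement membrane collagen gene COL4A3 (1.63 and 0.71), FBXL19-AS1 (1.29 and 0.75), PAPSS2 (0.79 and 0.77), GUCA1B (0.64 and 0.91), RASSF3 (0.61 and 0.68) and SOX30 (0.53 and 0.73). With the mean of its probes GUCA1B was lower in both. Lower in both were the epithelial transcription factor ELF3 (-0.78 and -1.47), the kinase gene GRK4 (-0.81 and -1.10), HIC1 (-1.15 and -0.74), ZNF687 (-0.66 and -0.93), SYCE2 (-0.62 and -0.81) and the integrin gene ITGA6 (-0.55 and -0.57). Averaged over pH, E2F targets had a median of 0.19, ribosome biogenesis genes 0.24 and metallothioneins -0.79, and each is what was left of medians of opposite sign at pH 7.4 and pH 6.8. In limma's additive model of pH and valproate over 17234 genes, with 1 residual degree of freedom, 0 genes passed an adjusted p of 0.05 for acid and 0 for valproate. At an unadjusted p of 0.05 there were 33 genes for acid and 24 for valproate, against 862 by chance alone. The model counts a departure from additivity as error, and in simulated data with such error it recovered 0% of genes with a true 4-fold difference.

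The interaction, the valproate difference at pH 6.8 minus that at pH 7.4, was above 1 for 2418 of 15586 genes well above background on all 4 arrays and below -1 for 2456. Highest among those with a symbol were PLD6 at 6.32, SLC5A12 at 6.0, the chemokine receptor gene CXCR3 at 4.94, the transferrin receptor gene TFRC at 4.42, LRRC24 at 4.31 and FAM3A at 4.26. Lowest among them were COXFA4L3 at -8.41, PGF at -8.22, CD52 at -7.99, BAIAP2-DT at -7.79, OBSL1 at -7.57 and PTPRF at -7.56. By group, ribosome biogenesis had a median interaction of 2.16 with 25 of 25 above 0, heat shock proteins 1.35, plasma cell genes 1.24, E2F targets 1.19, amino acid stress genes 1.08, metallothioneins -3.89, neuronal genes -1.59 and FOXO targets -1.16. The interaction had no residual degree of freedom and was not tested.

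The 2 acid differences share no array, and neither do the 2 valproate differences, so independent noise between spots gives a correlation of 0 across genes. That is no reference for single samples, since chance differences between 4 cultures along 1 shared axis can give a strong correlation of either sign. Across 15586 genes the acid differences without and with valproate had a Pearson r of -0.76 (Spearman's rho -0.67), and the valproate differences at pH 7.4 and at pH 6.8 an r of -0.87 (rho -0.83). Of 2612 genes at least 2-fold different in acid without valproate, 6.36% (exact 95% binomial interval 5.45 to 7.36%) had the same sign with valproate. Of 1969 genes at least 2-fold different with valproate at pH 6.8, 2.03% (1.46 to 2.76%) had the same sign at pH 7.4. Genes at least 2-fold different in both acid comparisons numbered 721 in opposite directions and 8 in the same direction, and for valproate 939 and 1. The intervals cover counting error only. The arrays most alike were pH 7.4 without valproate and pH 6.8 with valproate, with a standard deviation of the difference of 0.25 and 109 genes at least 2-fold apart, followed by pH 7.4 with valproate and pH 6.8 without valproate, with 0.39 and 391 genes. The largest distance was 0.81, between the arrays without valproate. The first of these pairs lay at positions 1 and 4 of the slide and the second at positions 2 and 3. Counting any of a gene's probes, 783 genes were well above background only at pH 7.4 with valproate and at pH 6.8 without it. Only on the other pair were 56. The lowest signal well above background was 12.2 and 12.3 on the arrays with 783 such genes and 15.5 and 15.4 on the others. Dim genes could pass more easily on the former, so these counts are no separate sign of likeness.

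**Figure D2:**
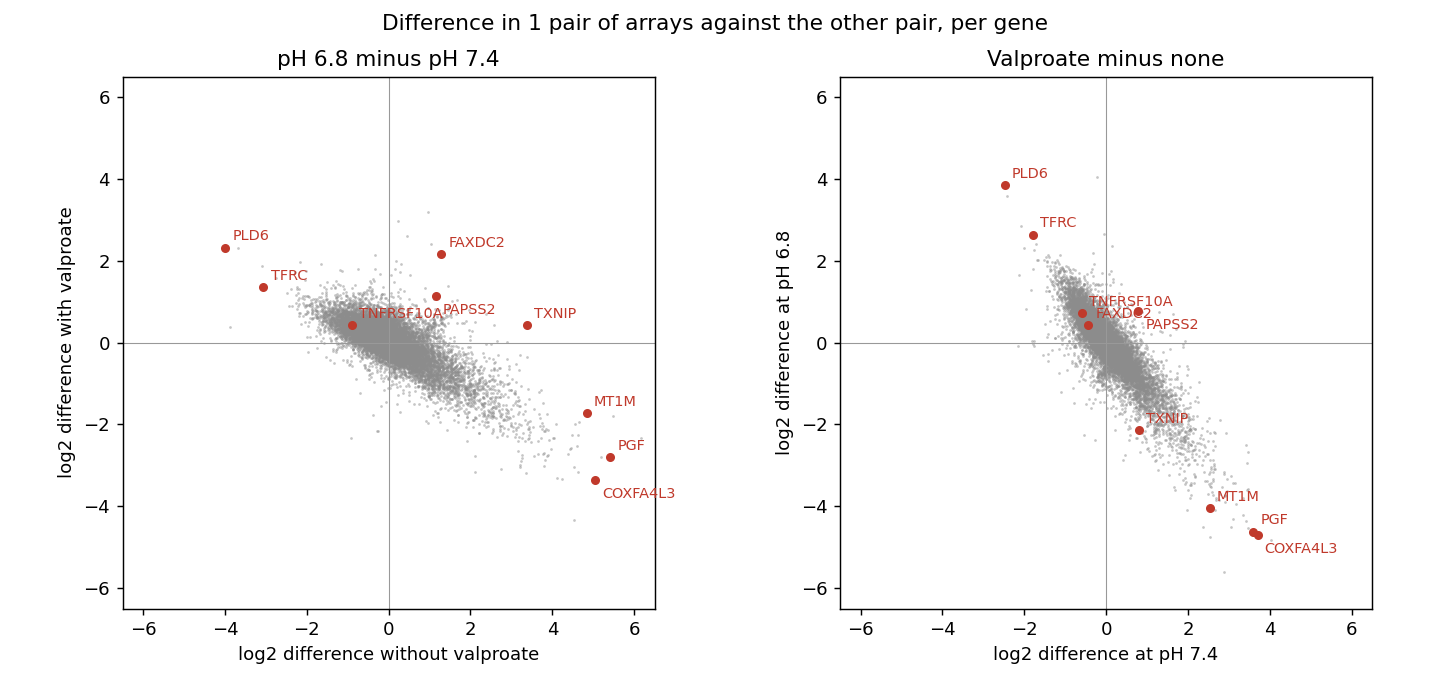
Each grey dot is 1 of 15586 genes well above background on all 4 arrays, with 1 array per group; the left panel plots the log2 difference between pH 6.8 and pH 7.4 with valproate against that without, and the right panel the log2 difference between valproate and none at pH 6.8 against that at pH 7.4. The clouds slope downward (r of -0.76 and -0.87), from PLD6 and TFRC at the upper left to PGF and COXFA4L3 at the lower right, while PAPSS2 lies above 0 on every axis.

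With the labels taken as given, the last comparison asked what valproate did at pH 6.8 to the genes that were lower in acid. An exchange of the valproate labels at pH 6.8 would change what both differences mean. Of 960 genes at least 2-fold lower at pH 6.8 without valproate, 955 (99.5%, exact interval 98.8 to 99.8%) were higher with valproate at pH 6.8, by a median of 1.06, which was a median of 85.6% of the acid difference. RRP9, for example, stood at -2.22 in acid and at 1.77 with valproate in acid, and TFRC at -3.06 and 2.64. Of 1652 genes at least 2-fold higher in acid, 1644 were lower with valproate, by a median of -1.30, including PFKFB4 (3.22 and -1.47), CA9 (2.39 and -1.26) and BMF, which promotes cell death (3.09 and -2.54). The 2 differences share the array at pH 6.8 without valproate, so part or all of this may be built in. Simulated data without any valproate difference gave 55.0% of genes higher with the noise between spots and 83.1% if the whole acid difference were noise, and genes picked on 1 probe and measured on another gave 189 of 199 (95%, 91.0 to 97.6%). Both probes read the same RNA on the same arrays, so a deviation of the 1 sample at pH 6.8 without valproate stays shared. The simulations drew independent noise of equal size for each array, so they do not cover such a deviation either. The correlation of the 2 differences was -0.95, against -0.51 in simulated data without any difference. Their covariance was -0.562, against -0.00374 in data simulated with the noise between spots, -0.0592 with noise 4 times as large and -0.332 if the whole acid difference were noise.

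The other differences with a shared array had like values; the simulated values here hold the noise between spots only, which cannot stand for the spread between separate samples. Acid without valproate and valproate at pH 7.4 had an r of 0.90 (simulated 0.49) and a covariance of 0.421 (simulated 0.00362), led by COXFA4L3, PGF and CD52, which are among the highest of both. Acid with valproate and valproate at pH 7.4 had an r of -0.90 (simulated -0.50) and a covariance of -0.269 (simulated -0.00362). Acid with valproate and valproate at pH 6.8 had an r of 0.86 (simulated 0.50) and a covariance of 0.322 (simulated 0.00368), and COXFA4L3 was among the 3 lowest genes with a symbol of both.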

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

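The tests of exchanged labels, of signal-dependent distortion and of RNA from other cells were chosen only after the result was seen; the test with spiked-in control RNA was written before its values were seen. Each result here was picked out because the difference in acid, or with valproate, ran in opposite directions in the 2 groups compared. With 1 array per group, none of these differences between groups was tested.

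The acid differences without and with valproate correlated at -0.76 across genes and the valproate differences at pH 7.4 and pH 6.8 at -0.87. At least 2-fold in both and in opposite directions were 721 genes for acid and 939 for valproate. Metallothioneins had a median valproate difference of 1.13 at pH 7.4 and -2.74 at pH 6.8. Ribosome biogenesis genes had -0.84 and 1.33, neuronal genes 0.88 and -1.02, and fibroblast markers 1.09 and -1.40. The TRAIL receptor gene TNFRSF10A had -0.60 and 0.72.

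For the opposite valproate differences, a candidate explanation is that the valproate labels of the 2 arrays at pH 6.8 are exchanged. Genes that histone deacetylase inhibitors raise in many cell types, listed from general knowledge before their own values were looked at but after the opposite profiles had been seen, had a median valproate difference of 0.72 (bootstrap interval over 11 measured genes 0.24 to 1.44) at pH 7.4 and -1.16 (-2.14 to -0.91) at pH 6.8; KIF5C stood at 1.44 and -3.73 and GSN at 0.85 and -2.14. MLLT11 was higher at both pH values (0.24 and 0.10) and GLRX lower at both (-0.08 and -0.35), while the others turned their sign. These values decide nothing between an exchange and a true reversal. The reason is that the correlation of -0.87 over all genes already largely fixes the sign at pH 6.8 for genes higher at pH 7.4. An exchange of the pH labels of the 2 valproate arrays would leave the average over pH positive for a drug active on these genes. That average was -0.31 (-0.65 to -0.15). The interval covers only the spread between genes, most of which move together. A deviation of the 1 sample at pH 6.8 without valproate could set the sign of the average, so it decides nothing either. The exchange of valproate labels stays open as a hypothesis. So does an exchange of pH labels. With a weak drug, the closeness of pH 7.4 without valproate and pH 6.8 with valproate (standard deviation 0.25) would allow it. If the labels are right, an effect of valproate that runs opposite ways at the 2 pH values stays open too and was not tested. A drug that only reverses an effect of acid would not account for the differences at pH 7.4. There, metallothioneins had a median valproate difference of 1.13 and ribosome biogenesis genes -0.84, each on the same side of 0 as in acid without valproate.

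For the spread of the interaction between genes, array position, labelling or hybridisation may be considered. The tables argue against them only where they act on spiked-in control RNA as on genes. The arrays lay at positions 1 and 2 of the slide (pH 7.4 without and with valproate) and 3 and 4 (pH 6.8 without and with valproate). The interaction thus sets positions 1 and 4 against 2 and 3. An effect of position that differs between genes but spares the 6 spiked-in probes stays open. Spiked-in control RNA, which enters at labelling, had a standard deviation of the interaction of 0.0577 over 6 probes (range -0.68 to -0.51), which was 4.51% of the 1.28 found over 12747 genes in the same range of signal. All 6 lay below 0 against a median of 0.18 over genes. A shift shared by all genes therefore stays open, and the counts above 1 and below -1 depend on it. The pairwise comparisons use the same scaling of each array. Their splits into higher and lower genes, and the signs of small list medians, may therefore depend on such a shift too. Percentiles among random lists do not, since a shared shift moves every list alike. The size of the shift in each pair was not tested. Distortion that depends on signal is argued against as the source of the opposite directions, since after centring within 20 bins of mean signal the valproate differences at the 2 pH values still correlated at -0.86. The differences did trend with signal. For acid without valproate the bin medians lay between 0.28, at a median signal of -2.97, and -0.38, at 4.43. List medians carry this trend, which only the random lists matched on signal allow for. Differences between the cultures or RNA samples that arose before labelling stay open, because each condition has 1 sample, and so does a biological interaction of acid and valproate, which was not tested.

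For markers of other cell types at pH 6.8 without valproate, RNA of other cells in the culture may be considered. The first test asked whether 11 abundant transcripts of stromal, erythroid and myeloid cells lay among the brightest 10% of genes; it left the question open, because HBB lay at percentile 91.4 of signal on that array, with an acid difference of -0.60, while the other 10 lay at or below percentile 36.8, 5 of them well above background on 0 arrays. A narrower test of stromal RNA, added after that, decided nothing: COL3A1, SPARC and FN1 were well above background on 0 arrays, so the percentile of the highest, SPARC at 4.94, ranks background signal. RNA of stromal cells stays open, and so do RNA of T, NK or B cells, which was not tested, and expression of these genes by the INA6 cells themselves.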

How the results depend on the processing

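Normexp on the median signal, with outlying local backgrounds replaced, was added after seeing the data; the other alternatives were planned. Planned but not run were normexp on the mean signal, which the files lack, and the slide as a block, since 1 slide holds all 4 arrays. No paired analysis was possible because each group has 1 array. Counts are given as genes higher, then lower, for acid without valproate, acid with valproate, valproate at pH 7.4 and valproate at pH 6.8. With normexp they were 1116 and 684, 98 and 330, 456 and 118, 438 and 888. Among genes well above background on all 4 arrays, a smaller set, 1652 were higher in acid without valproate, 175 higher and 718 lower in acid with valproate, 945 and 205 with valproate at pH 7.4, and 1302 lower with valproate at pH 6.8. Without a filter on background, over 27771 genes and features, 4102 were higher in acid without valproate, and the other counts were 1433 and 2114, 2630 and 969, 1734 and 3376; the interaction was above 1 for 4168 and below -1 for 5172. At 1.5-fold the counts were 4221 and 3183, 1876 and 2373, 2845 and 1811, 2909 and 3633, with 4701 and 3704 for the interaction. At 4-fold they were 763 and 105, 125 and 188, 258 and 71, 125 and 607, with 334 and 1100 for the interaction. The same-sign share of acid was 3.39% with normexp and 20.9% without a filter, and that of valproate 0.533% and 17.2%, and 2.99% with the mean of a gene's probes. Acid-lowered genes higher with valproate were 100.0% with normexp and 94.1% without a filter. Of the values of named genes, 52 were at least 2-fold with normexp, against 89. The proton, lactate and bicarbonate transport list had a median of -0.05 with valproate at pH 7.4 among genes well above background on all 4 arrays, against 0.20, since fewer members enter. Where no reason is given the cause was not tested. Under quantile normalization and the series table all these results stayed within 1.5 times the main count or within its interval, and the correlations of -0.76 and -0.87 lay between -0.75 and -0.76 and between -0.85 and -0.89 under every scaling, background correction and probe rule tried; without a filter they were -0.47 and -0.55. In limma 0 genes passed an adjusted p of 0.05 under any setting; at an unadjusted p of 0.05 the counts for acid ran from 12 (all 4 arrays) to 586 (no filter) and for valproate from 2 to 488, and at an adjusted p of 0.1 without a filter 1 gene passed for each. Of 722 medians of lists and values of named genes, 280 moved with quantile normalization, 293 with normexp and 99 with the mean of a gene's probes by more than the spread of random lists or of spots, and 0 moved with the series table. Signal over background limits the counts, since 880 of the 2561 genes higher in acid without valproate have only a bound.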

Other observations

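The families in this part, and the genes named in them, were chosen after their values were seen, from a look over symbol families, so their percentiles are a description only. Mitochondrial ribosomal protein genes had medians of the same sign as ribosome biogenesis, but smaller. All 75 were lower at pH 6.8 without valproate, 19 at least 2-fold, with a median of -0.73, and 73 of 75 were higher with valproate at pH 6.8, with a median of 0.56; MRPL12 stood at -1.18 and 1.03. RNA polymerase subunit genes were lower in 29 of 29 cases with a median of -0.80 and then higher in 27 of 29 with a median of 0.65, and the subunits of RNA polymerase I POLR1G (-2.26 and 2.02) and POLR1C (-2.05 and 1.83) stood furthest out. Small nucleolar RNA host genes were lower in 15 of 15 cases with a median of -1.21 and higher in 15 of 15 with a median of 0.57, with SNHG15 at -1.81 and 1.70. The median of -1.21 was -0.59 with normexp and -0.85 with quantile normalization, under which those of the mitochondrial ribosome and RNA polymerase families were -0.46 and -0.53. The medians of these 3 families lay below all 10000 random lists matched on signal in acid without valproate.

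The proteins of the cytosolic ribosome did not share the size of that difference. Their 77 genes had a median of -0.13 in acid without valproate and 0.11 with valproate at pH 6.8. With quantile normalization these medians were -0.01 and 0.02. Among random lists matched on signal the main medians lay at percentiles 98.8 and 0.77, but that matching was coarse. Over all genes, those at a median signal of 6.26 had medians of -0.16 and 0.13, against -0.38 and 0.28 at 4.43. The percentiles therefore do not show a difference from equally bright genes. Proteasome subunits had -0.58 and 0.40 (-0.27 and 0.18 with quantile normalization), with PSMB5 at -1.29 and 0.99, and the chaperonin that folds actin and tubulin had -0.80 and 0.64, with 8 of 8 lower and 8 of 8 higher. Zinc finger genes named ZNF had medians of 0.03 and -0.02 over 384 genes, which turned to -0.14 and 0.08 with quantile normalization; the other families kept the sign of both medians under every scaling tried. No explanation was tested for these families.

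Among the proton-sensing receptors, GPR4 was well above background, by any of its probes, on both arrays at pH 6.8 and on neither at pH 7.4. It is 1 of 123 genes with that pattern, against 38 genes well above background on both arrays at pH 7.4 and on neither at pH 6.8, with 1 array per group and so no error for these counts.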
